A study of Mus musculus with 12 samples.

How the data were processed

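RNA from the pooled left and right hippocampi of 12 mice, 3 in each of the groups SUMO1tg, WT1, SUMO2tg and WT2, was measured on Affymetrix whole-transcript mouse arrays. Per the labels' protocols, biotin-labelled targets were made from 100 ng of total RNA purified with TRIZOL and a column cleanup. The deposited values are normalized intensities, 1 column per animal, for 28853 probe sets. Per the submitters' processing notes, RMA and Partek were used, with no version, role or order given, and the array build and any further filters are not stated. The deposited intensity values are on a linear scale, since no value is negative and the medians of the arrays lie between 99.3 and 104.4, so their log2 was taken. No background measurement or detection call was used here, so how far a value lies above background is not known, and the number of arrays limits the precision.

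Of the 28853 probe sets, 23410 were in the probe table, 21789 of them with 1 gene symbol and 1621 with several, and 5443 were not listed. Of the probe sets with 1 symbol, 21698 matched a current symbol in the RefSeq gene table for assembly GRCm38.p6, and 0 symbols changed. That table was used only for names and for which genes neighbour each other. Tested were the probe sets with 1 symbol whose mean over all arrays lay above the lowest 33.3% (a log2 mean of 5.92, an intensity of 60.5), which left 14526 probe sets of 13208 genes. Of these, 53 held the same values as an earlier probe set. Where a gene had several probe sets, statements on the gene and the gene lists used the one with the highest mean over all arrays. The 7064 probe sets with several symbols or none were tested apart, and 0 passed in each of the comparisons at an adjusted p under 0.05 in limma, where 627 in SUMO1tg against WT1 and 260 in SUMO2tg against WT2 had an unadjusted p under 0.05.

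Statistics were computed in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. A mean per group was fitted to the log2 values of all 12 arrays (8 residual degrees of freedom, 4.15 prior degrees of freedom), contrasts were taken for SUMO1tg minus WT1, SUMO2tg minus WT2, the difference of these changes, and WT2 minus WT1, variances were moderated with eBayes, and p-values were adjusted by Benjamini and Hochberg over the probe sets tested. A probe set passed at an adjusted p under 0.05. Sumo2 and Sumo3 also had an exact two-sided permutation test, whose smallest p is 0.1 for 3 against 3 arrays. For 29 lists of genes (pathways, cell types, hippocampal regions, neighbouring tissues and sex-linked transcripts), limma's camera with a preset correlation of 0.01 compared each list with the other genes. Camera with an estimated correlation and fry were run beside it, and p-values were adjusted over the 28 lists with at least 5 tested genes. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3.

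The groups, comparisons, tests, thresholds, gene lists, the alternatives given below, apart from the fits named as added, and the rule for naming genes were fixed before the data were examined. The rule named Sumo1, Sumo2 and Sumo3. For each line and for the difference of the lines it also named the 10 genes with the largest change in each direction among those that passed, with places left over filled in order of unadjusted p. For the wild types it named 5 in each direction. In the comparisons of groups, arrays of named genes had not to overlap, and predicted genes without a proper name were skipped. From each list described, up to 4 members with the lowest p were named. The fit was tested on simulated data with the 14526 probe sets, in which 50 probe sets were changed at each of the sizes 0.5, 1, 1.5 and 2 log2 together. The noise was drawn independently for each probe set. For SUMO1tg against WT1 it recovered 78% of those changed by 0.5 log2 and 96% of those changed by 1, with 10 false calls. For SUMO2tg against WT2 it recovered 72% and 94%, with 12 false calls. With so many probe sets changed at once the adjusted threshold is easier to reach. These shares therefore do not give the recovery of a single changed gene among unchanged ones.

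The alternatives were fitting only the groups compared, no filter or a stricter filter on dim probe sets, quantile normalization, centring each array on its median, a variance trend with robust moderation, no moderation, array weights, the replicate number as a block, all rows of the table, the mean over a gene's probe sets, other thresholds, other wild types as the reference, and leaving out each array in turn. Fits without WT1 array 3 and WT2 array 1, with choroid plexus and thalamic marker levels as covariates, and with the Xist level as a covariate were added after the data had been examined. No array was left out of the main comparisons. No coordinates are given, since the deposited files name no genome build.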

Results

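Gene expression was measured in the hippocampus of 12 mice with Affymetrix whole-transcript mouse arrays, 1 array per animal. The animals formed 4 groups of 3: mice carrying a SUMO1 transgene (SUMO1tg), mice carrying a SUMO2 transgene (SUMO2tg), and a set of wild types for each line (WT1 for SUMO1tg and WT2 for SUMO2tg, as the series description pairs them). The litter labels give SUMO1tg and SUMO2tg both the number of WT1, so whether WT2 are littermates of SUMO2tg is not known. SUMO proteins are small ubiquitin-like modifiers that are attached to lysines of other proteins. Per the labels, all animals were C57bl6/N mice of 8 to 12 weeks, and the left and right hippocampi of an animal were pooled. The labels also give each sample a range of zeitgeber time, the hours since lights on, whose start is shared and whose end rises by 1 from each sample to the next through WT1, SUMO1tg, WT2 and SUMO2tg, as in a series filled down a spreadsheet column. Whether these were the times of collection is therefore doubtful, and if so, they cannot be told apart from the groups. The deposited table held 28853 probe sets, and 14526 probe sets of 13208 genes were tested. Median intensities of the 12 arrays lay between 99.3 and 104.4, and each array's mean correlation with the other arrays lay between 0.986 and 0.993. The number of arrays limits the precision of every value below, and the table holds no measurement of background signal. Xist, the transcript that silences an X chromosome in females, had an intensity of 859, 948, 876 and 898 on 1 array of WT1, SUMO1tg, WT2 and SUMO2tg and of 17.7 to 24.6 on the other arrays.

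Sumo2 transcripts had higher mean intensities in SUMO2tg than in WT2 on all 5 probe sets of the gene, by 0.17 to 0.23 on the log2 scale. Against WT1, whose litter number the SUMO2tg labels carry, 4 of the 5 were higher, by 0.11 to 0.21, the brightest by 0.11 (limma adjusted p = 0.63), and probe set 10520124 differed by -0.03. The brightest Sumo2 probe set (10438454) read 2938 ± 16.7 in SUMO2tg and 2610 ± 103.9 in WT2 (mean intensity ± SD, n = 3 each), and its 3 SUMO2tg arrays all lay above the 3 WT2 arrays. This Sumo2 difference of 0.17 ± 0.06 log2 (SE) did not pass the limma test over all probe sets (adjusted p = 0.999), and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 arrays allow. Probe set 10392947 had the largest Sumo2 difference, 0.23 ± 0.05 against WT2 (limma adjusted p = 0.454). It differed by 0.21 from WT1 (limma adjusted p = 0.251) and by 0.22 from all 6 wild types (limma adjusted p = 0.161), and did not pass either. Sumo3, which encodes a protein nearly identical to the Sumo2 product, read 915 ± 66.3 in SUMO2tg and 667 ± 23.8 in WT2 on its single probe set (10364287). The Sumo3 difference was 0.45 ± 0.08 log2 (1.37-fold, limma adjusted p = 0.21), and against all 6 wild types it was 0.47 and passed (limma adjusted p = 0.0407), while against WT1 it was 0.48 and did not pass (limma adjusted p = 0.0735). Sumo2 on its brightest probe set differed by 0.14 from all 6 wild types (limma adjusted p = 0.879). In SUMO1tg, the brightest Sumo2 probe set differed from WT1 by 0.0024 ± 0.06 log2 and 1 of the other 4 by -0.15, and Sumo3 differed by 0.14 ± 0.08 (limma adjusted p = 0.65). Between the changes of the lines, SUMO1tg minus SUMO2tg, Sumo2 differed by -0.17 and Sumo3 by -0.31 (limma adjusted p = 0.924 for both), Sumo2 by -0.085 after quantile normalization. Between WT2 and WT1, Sumo2 differed by -0.06 and Sumo3 by 0.02. None of the 23410 probe sets in the probe table carried Sumo1, alone or among several symbols, and 5443 probe sets were not listed there, so whether any probe set reads Sumo1 is not known and the SUMO1 transgene was not checked by its own gene. The files give neither the transgene sequences nor the probe sequences, so which of these probe sets read a transgene, or the other family member, was not resolved.

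SUMO1tg was compared with WT1 to ask which hippocampal transcripts differed between SUMO1 transgenic mice and their wild-type littermates. Dusp1, a phosphatase that inactivates MAP kinases, had the largest difference among the 10 top-ranked genes with a higher mean, at 0.75 ± 0.16 log2 (1.69-fold, SE, n = 3 per group). Pvr, a cell adhesion molecule related to the nectins, differed by 0.48 ± 0.07 (1.39-fold) and the hydrolase gene Abhd1 by 0.50 ± 0.08 (1.41-fold), and they had the lowest adjusted p-values among named genes (limma, 0.231 and 0.235). The other genes ranked highest on this side were Tfr2, the second transferrin receptor (0.42), Zscan21 (0.37), Bnip5 (0.35), Rep15 (0.34), the transcriptional repressor Etv3 (0.30), Clic5 (0.28) and Gmppb, which makes GDP-mannose (0.26). With a lower mean in SUMO1tg, the 10 highest-ranked genes were, in order of p, the protocadherin Pcdhb2 (-0.26), Odc1, the rate-limiting enzyme of polyamine synthesis (-0.46 ± 0.12, 1.37-fold), Zbtb32 (-0.21), Cyp2d40 (-0.45), Taf8, a subunit of a general transcription factor (-0.23), the mitotic kinase Plk1 (-0.27), Nid2, a basement membrane protein (-0.41), Ppp1r32 (-0.21), the translation factor Eif5a (-0.24) and AA414768 (-0.27). None of these 20 genes passed the test. Against all 6 wild types in place of WT1, Zscan21 differed by 0.19, Bnip5 by 0.18, Pcdhb2 by -0.11 and Cyp2d40 by -0.28, and Nid2 differed by -0.24 without WT1 array 3 and Eif5a by -0.16 without WT1 array 2. Over all its alternative fits, Odc1 lay between -0.61 and -0.30. Of the 14526 probe sets, 0 reached an adjusted p under 0.05 in limma, and 0 did so without moderated variances. At an unadjusted p under 0.05 there were 1087 probe sets, 854 with higher and 233 with lower means in SUMO1tg, where chance gives 726.3. This surplus was not particular to SUMO1tg. With WT1 as the reference, WT2 gave 1229 (960 higher and 269 lower) and SUMO2tg 1229 (982 higher and 247 lower). These comparisons share the WT1 arrays. Against all 6 wild types, SUMO1tg gave 812 (576 higher and 236 lower). The 3 arrays of each group did not overlap on 10.2% of probe sets, and chance gives 10%. Over all tested probe sets, the median difference was 0.03 log2 in SUMO1tg against WT1 and in WT2 against WT1. It was 0.0018 in SUMO2tg against WT2 and 0.03 for the difference of the changes. Counts of higher and lower means are therefore not centred on 0 where WT1 is the reference.

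Among the gene lists, markers of choroid plexus and ependyma, the epithelium that makes cerebrospinal fluid and the cells lining the ventricles, had the lowest median in SUMO1tg: 19 of 20 genes had lower means than in WT1, with a median of -0.71 log2 (camera adjusted p = 1.28e-10, but adjusted p = 0.833 with an estimated correlation). The members with the lowest p were Tmem72 (-0.88), the channel Trpv4 (-0.49) and the potassium channel subunits Kcne2 (-0.95) and Kcnj13 (-2.32). The mean level of this list, centred over all arrays, was 1.29 on WT1 array 3 and between -0.63 and -0.02 on the other 5 arrays of these groups. Activity-induced immediate early genes, which neurons transcribe within minutes of firing, were shifted higher: 27 of 34 had higher means, with a median of 0.17 (camera adjusted p = 0.00612, but adjusted p = 0.833 with an estimated correlation). Of these, Dusp1 (0.75), Sik1 (0.38), Ier2 (0.32) and Ccn1 (0.27) had the lowest p, and 1 gene passed when adjusted over the list alone, against 0 over all probe sets. Markers of GABAergic interneurons were shifted higher as a set, with 21 of 23 above WT1 and a median of 0.12 (camera adjusted p = 0.019, but adjusted p = 0.833 with an estimated correlation), among them the neuropeptide genes Tac1 (0.58), Sst (0.47) and Vip (0.26) and the secreted ligand Nxph1 (0.23). Markers of oligodendrocytes and myelin were shifted lower, with 17 of 19 below WT1 and a median of -0.10 (camera adjusted p = 0.00544, but adjusted p = 0.833 with an estimated correlation); Sox10 (-0.13), Ugt8a (-0.20), Trf (-0.21) and Cnp (-0.19) had the lowest p. Meningeal markers (10 of 14 lower, median -0.10, camera adjusted p = 0.019, but adjusted p = 0.833 with an estimated correlation), with Igf2 (-0.60), Slc13a4 (-0.66), Igfbp2 (-0.53) and Mgp (-0.15), were shifted lower too. So were markers of CA3 and CA2 pyramidal neurons (13 of 18 lower, median -0.08, camera adjusted p = 0.0241, but adjusted p = 0.833 with an estimated correlation), with Map3k15 (-0.31), Iyd (-0.33) and Cacng5 (-0.24), although Nnat had a difference of 0.42. Heat shock and unfolded protein response genes had 21 of 25 lower means and a median of -0.03 (camera adjusted p = 0.0221, but adjusted p = 0.833 with an estimated correlation), with Pdia4 (-0.16) and Hsp90b1 (-0.08) lower and Bag3 (0.19) and Herpud1 (0.18) higher. No gene of these 6 lists other than the immediate early genes passed when adjusted over the list alone (0 in each). All 7 calls thus rest on the preset correlation of camera, and 0 lists passed in fry.

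Single arrays decided part of these list calls in SUMO1tg. Without WT1 array 3, the choroid plexus median was -0.21 and still called, while myelin markers had a median of 0.03 (adjusted p = 0.947), interneuron markers 0.05 (adjusted p = 0.52), CA3 and CA2 markers -0.02 (adjusted p = 0.49) and meningeal markers -0.0081 (adjusted p = 0.947); the immediate early median was then 0.11. Without SUMO1tg array 3, the adjusted p was 0.393 for myelin, 0.169 for interneuron and for CA3 and CA2 markers, and 0.0537 for meningeal and heat shock genes. The immediate early call ended without WT1 array 1 (median 0.12, adjusted p = 0.394) or SUMO1tg array 1 (0.12, adjusted p = 0.085). The meningeal call also ended without SUMO1tg array 2 (adjusted p = 0.161), the heat shock call without WT1 array 1 (0.0558), WT1 array 2 (0.0587) or SUMO1tg array 1 (0.065), and the CA3 and CA2 call without WT1 array 2 (0.0587). Called medians moved by more than 1.5 times without WT1 array 1 for myelin (-0.20) and interneuron markers (0.20), without SUMO1tg array 1 for myelin (-0.18) and meningeal markers (-0.17), and without WT1 array 3 for heat shock genes (-0.04). Named members moved as well. Without WT1 array 3, the choroid plexus markers differed by -0.42 for Tmem72, -0.17 for Trpv4, -0.34 for Kcne2 and -1.43 for Kcnj13. The meningeal markers then differed by -0.17 for Igf2, -0.13 for Slc13a4, -0.03 for Igfbp2 and -0.07 for Mgp, and the myelin markers by -0.02 for Ugt8a, -0.07 for Trf and -0.04 for Cnp. Without this array, the CA3 and CA2 markers differed by -0.10 for Map3k15, -0.07 for Iyd, -0.04 for Cacng5 and 0.16 for Nnat. Interneuron markers differed by 0.23 for Sst, 0.13 for Vip and 0.09 for Nxph1, and heat shock genes by -0.08 for Pdia4, -0.05 for Hsp90b1 and 0.11 for Herpud1. Without SUMO1tg array 3, Sox10 differed by -0.08, Ugt8a by -0.09, Trf by -0.05 and Cnp by -0.08. Without WT1 array 2, Ccn1 differed by 0.17, Bag3 by 0.11, Sox10 by -0.19, Hsp90b1 by -0.14, Mgp by -0.24 and Igfbp2 by -0.81. Without SUMO1tg array 2, Mgp differed by -0.09. Without WT1 array 1, Map3k15 differed by -0.51, Iyd by -0.53, Cacng5 by -0.38, Nnat by 0.66, Vip by 0.40, Nxph1 by 0.35, Ugt8a by -0.35 and Cnp by -0.36. Against all 6 wild types, the immediate early median was 0.08 and the myelin median -0.17, both still called, and the heat shock median was -0.0027 (adjusted p = 0.386). Over all alternatives, fry and the estimated correlation included, the immediate early call was lost in 6 of 21 and the heat shock and meningeal calls in 8 of 21 each. The interneuron and the CA3 and CA2 calls were lost in 7 of 21 each, the myelin call in 3 of 21 and the choroid plexus call in 2 of 20. The median reversed in 3 for myelin, 1 for meningeal and 1 for CA3 and CA2 markers. In 1 of the myelin reversals, with marker levels as covariates, the median was 0.09 and the list was called (camera adjusted p = 0.0182).

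SUMO2tg was compared with WT2 to ask the same of SUMO2 transgenic mice. Penk, which encodes the precursor of the enkephalin opioid peptides, rose in SUMO2tg by 1.22 ± 0.15 log2 (2.32-fold, SE, n = 3 per group, limma adjusted p = 0.041) on its probe set (10511363), with all 3 SUMO2tg arrays (10.4 to 10.6 log2) above all 3 WT2 arrays (9.03 to 9.40). Mc4r, a melanocortin receptor, had the next largest difference among the 10 top-ranked genes with a higher mean, at 0.83 ± 0.15 (1.78-fold), but did not pass (limma adjusted p = 0.252). The protocadherin Pcdhb6 differed by 0.61 ± 0.10 (1.53-fold) and the zinc finger gene Zfp110 by 0.33 ± 0.05 (1.26-fold), with the same adjusted p as Sumo3 (limma, 0.21). Plp2 (0.53 on the brightest of its 3 probe sets), the cell surface protein gene Cd24a (0.43), Syna, an envelope gene of retroviral origin (0.39), the spindle gene Ska2 (0.29) and Tmem161b (0.29) did not pass either. With a lower mean in SUMO2tg, the 10 highest-ranked genes also did not pass: D3Ertd751e (-0.45), Leng9 (-0.28), Parvg (-0.39), the receptor Gpr3 (-0.39), the matrix protein gene Fbln5 (-0.34), Gfra1, a receptor for glial cell line-derived neurotrophic factor (-0.42), Ctxn3 (-0.29), the coactivator Ppargc1b (-0.23), the potassium channel subunit Kcnab3 (-0.28) and the calcium sensor Syt2 (-0.48). In limma, Penk was the 1 probe set of 14526 at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 539, 287 higher and 252 lower, where chance gives 726.3, and the groups did not overlap on 9.69% of probe sets, where chance gives 10%. The Penk call was lost when each of the 6 arrays was left out in turn: limma adjusted p = 0.135, 0.245 and 0.131 without WT2 arrays 1, 2 and 3, and 0.267, 0.215 and 0.276 without SUMO2tg arrays 1, 2 and 3, with differences of 1.10 to 1.29. It was also lost with only these groups in the fit (adjusted p = 0.1), without the filter on dim probe sets (0.056), after quantile normalization (0.0615), with a variance trend (0.0978) and without moderated variances.

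**Figure D1:**
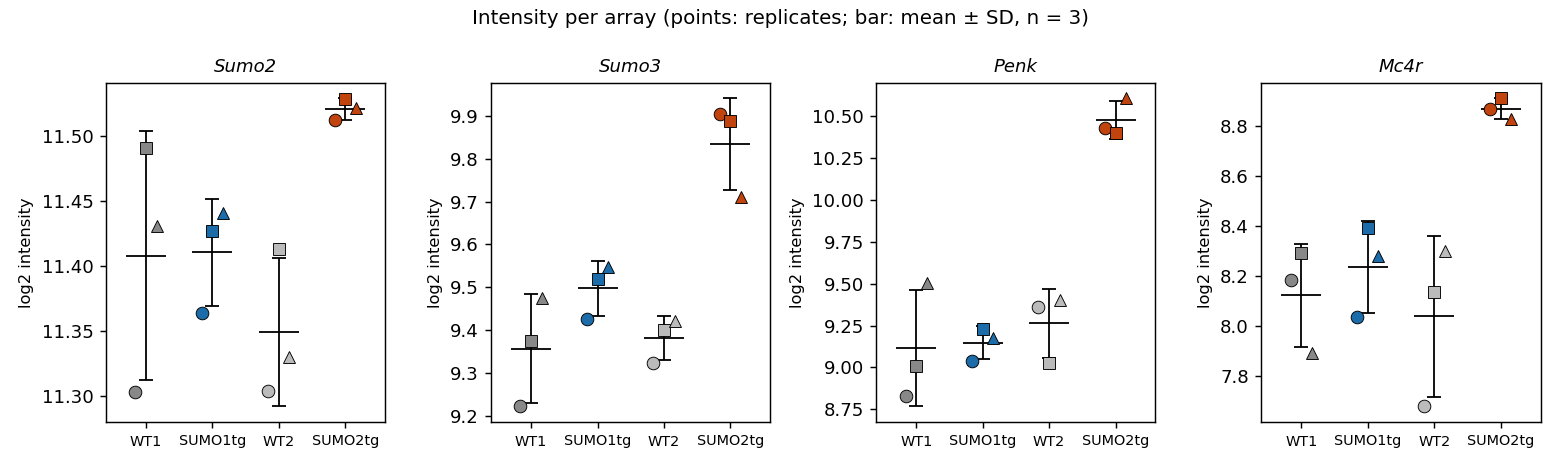
Log2 intensity of Sumo2 (brightest probe set), Sumo3, Penk and Mc4r (y axis) on each of the 12 arrays, by group (x axis). Points are arrays, bars are group means and error bars are ± 1 SD (n = 3). Penk lies between 10.4 and 10.6 in SUMO2tg and between 8.83 and 9.5 in the 9 other arrays.

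The series description pairs SUMO2tg with WT2, whereas the titles and litter labels give the SUMO2tg animals the litter number of WT1. SUMO2tg was therefore also set against WT1, where Penk rose by 1.36 log2 (limma adjusted p = 0.00604) and 5 probe sets passed. The 4 others, named here after their values were seen, were Scg5, Gm1976 (0.40), Gm33152 (-0.33) and Zfp110 (0.36). Scg5 read 10.31 log2 in SUMO2tg, 10.30 in WT2 and 10.91 in WT1, and Gm33152 differed by -0.33 between WT2 and WT1. These differences from WT1 were thus shared by WT2 and were not particular to the transgenic animals. Gm1976 differed by 0.11 between WT2 and WT1, and Zfp110 read 7.51 in WT2 and 7.48 in WT1. Among the other genes named for SUMO2tg with a higher mean, Pcdhb6 differed from WT1 by only 0.11, Cd24a by 0.20 and Tmem161b by 0.05. All 10 genes named with a lower mean shifted toward or past 0 by more than 1.5 times: D3Ertd751e to -0.29, Parvg to -0.25, Syt2 to -0.23, Gfra1 to -0.21, Gpr3 to -0.16, Fbln5 to -0.14, Ctxn3 to -0.13, Ppargc1b to -0.08, Leng9 to -0.04 and Kcnab3 to 0.05. Against all 6 wild types, 4 probe sets passed, all higher in SUMO2tg: Penk (1.29), Gm1976 (0.35), Zfp110 (0.35) and Sumo3 (0.47).

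Among the gene lists, markers of oligodendrocytes and myelin were shifted lower in SUMO2tg: 19 of 19 genes had lower means than in WT2, with a median of -0.23 log2 (camera adjusted p = 1.34e-07, but adjusted p = 0.796 with an estimated correlation), and Aspa (-0.46), Ermn (-0.34), Cnp (-0.32) and Sox10 (-0.16) had the lowest p. Thalamic markers, included to show tissue from beneath the hippocampus, had 15 of 15 lower means and a median of -0.58 (camera adjusted p = 6.34e-06, but adjusted p = 0.796 with an estimated correlation), with the vesicular glutamate transporter Slc17a6 (-1.38), Calb2 (-0.69), Plekhg1 (-0.60) and Rgs16 (-0.58). Their mean centred level was 1.38 on WT2 array 1 and between -0.23 and -0.04 on the 11 other arrays, and Slc17a6 read 10.4 log2 on WT2 array 1. Immediate early genes were shifted lower, with 30 of 34 below WT2 and a median of -0.11 (camera adjusted p = 6.34e-06, but adjusted p = 0.796 with an estimated correlation), among them Fosb (-0.44), Egr2 (-0.41), Sik1 (-0.29) and Nr4a3 (-0.18). Clock genes had 15 of 19 lower means and a median of -0.07 (camera adjusted p = 0.00549, but adjusted p = 0.796 with an estimated correlation), with Arntl (-0.23), Per1 (-0.21), Bhlhe41 (-0.21) and Hlf (-0.18), in animals whose labelled times differ between the groups, although that label may be a filled-down series. Meningeal markers (12 of 14 lower, median -0.15, camera adjusted p = 0.00775, but adjusted p = 0.965 with an estimated correlation) included Ptgds (-0.36), Mgp (-0.20), Slc22a6 (-0.15) and Bgn (-0.10). Endothelial and mural cell markers (13 of 20 lower, median -0.07, camera adjusted p = 0.0259, but adjusted p = 0.965 with an estimated correlation) included Vtn (-0.18), Acta2 (-0.18), Tie1 (-0.16) and Esam (-0.13). No gene of these 6 lists passed when adjusted over the list alone (0 in each). None of the 6 calls held with an estimated correlation, and 0 lists passed in fry. Choroid plexus markers had a median of 0.0014 in SUMO2tg, with 10 of 20 higher (camera adjusted p = 0.975). Of 28 SUMO conjugation and deconjugation genes, 12 had higher and 16 lower means, with a median of -0.02 (camera adjusted p = 0.893). Sumo3 passed when adjusted over that list alone, and Sumo2 (0.17), Rwdd3 (0.18) and Nsmce2 (-0.11) followed. In fry's test of change in either direction, the SUMO list passed (adjusted p = 0.0208). So did striatal markers (adjusted p = 0.000347), whose 11 genes had a median of -0.0099 and included Penk (1.22), Scn4b (-0.58), Rasd2 (-0.19) and Pde10a (0.11). The SUMO list holds Sumo2 and Sumo3, whose probe sets may read the transgene, and the striatal list holds Penk. These passes in fry are not shown to hold without those genes. In SUMO1tg the same SUMO list had a median of 0.03 (17 of 28 higher, camera adjusted p = 0.965), with Zmiz1 (0.19), Sumo3 (0.14), Pml (0.12) and Rangap1 (0.09). All tested probe sets together had a median of 0.03 there too. Without each array in turn, Zmiz1 lay between 0.11 and 0.29, Sumo3 between 0.07 and 0.20, Pml between 0.07 and 0.17 and Rangap1 between 0.07 and 0.13.

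Single arrays decided part of the list calls in SUMO2tg as well. Without WT2 array 1, thalamic markers had a median of 0.0044 (adjusted p = 0.943), clock genes -0.03 (adjusted p = 0.0556) and meningeal markers -0.07 (adjusted p = 0.0649), and myelin markers stayed called at -0.12. The endothelial median was then -0.03 and still called. Without SUMO2tg array 1, the immediate early median was -0.05 and still called, and the clock (-0.04, adjusted p = 0.0711) and meningeal calls (-0.08, adjusted p = 0.185) ended. The endothelial call ended without WT2 array 2 (adjusted p = 0.444), SUMO2tg array 2 (0.113) or SUMO2tg array 3 (0.0703). The thalamic median was -0.37 without SUMO2tg array 3 and the clock median -0.11 without WT2 array 3, both still called. Of the named members, without WT2 array 1 Slc17a6 differed by -0.49, Plekhg1 by -0.11, Rgs16 by -0.07 and Calb2 by -0.40. Without the same array, Aspa differed by -0.21, Ermn by -0.21 and Cnp by -0.15. Sik1 then differed by -0.12, Egr2 by -0.17 and Nr4a3 by -0.10, Arntl by -0.13, Ptgds by -0.22 and Scn4b by -0.28. Without WT2 array 2, Acta2 differed by -0.09, Vtn by -0.08, Esam by -0.07 and Slc22a6 by -0.09. Without SUMO2tg array 1, Ptgds differed by -0.09, Mgp by -0.12, Slc22a6 by -0.10, Scn4b by -0.35 and Rwdd3 by 0.12. Without WT2 array 3, Slc17a6 differed by -2.11, Rgs16 by -0.92, Fosb by -0.68 and Vtn by -0.28. Without SUMO2tg array 2, Sox10 differed by -0.09 and Slc22a6 by -0.28, and without SUMO2tg array 3 Calb2 by -0.37 and Slc22a6 by -0.09. Against WT1 in place of WT2, immediate early genes had a median of 0.02, clock genes 0.06 and thalamic markers -0.0014, none of them called, and myelin markers -0.08, still called (camera adjusted p = 0.00624, but adjusted p = 0.966 with an estimated correlation). Among list members that moved by more than 1.5 times, Sik1 differed from WT1 by -0.02, Fosb by -0.08, Nr4a3 by -0.11, Egr2 by 0.0023, Per1 by -0.0002, Bhlhe41 by -0.11 and Hlf by 0.10. Further members that moved as far were Aspa (-0.18), Ermn (-0.17), Cnp (-0.14), Sox10 (-0.28), Mgp (-0.30), Scn4b (-0.23), Rwdd3 (0.04) and Nsmce2 (-0.18). The others were Slc17a6 (0.06), Calb2 (-0.0044), Plekhg1 (-0.01), Rgs16 (-0.06), Vtn (0.05), Esam (0.05), Tie1 (-0.02) and Bgn (-0.0012). Choroid plexus markers were lower in SUMO2tg than in WT1 (20 of 20, median -0.30, camera adjusted p = 0.000334, but adjusted p = 0.966 with an estimated correlation), as were heat shock genes (17 of 25, median -0.05, camera adjusted p = 0.00373, but adjusted p = 0.966 with an estimated correlation). Endothelial and mural cell markers (14 of 20 lower, median -0.09, camera adjusted p = 0.00174, but adjusted p = 0.966 with an estimated correlation) and meningeal markers (12 of 14 lower, median -0.12, camera adjusted p = 0.000668, but adjusted p = 0.966 with an estimated correlation) stayed called against WT1. Against all 6 wild types, the immediate early median was -0.04, the myelin median -0.15 and the thalamic median -0.27, all still called, and the clock median was -0.0012 (adjusted p = 0.298).

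**Figure D2:**
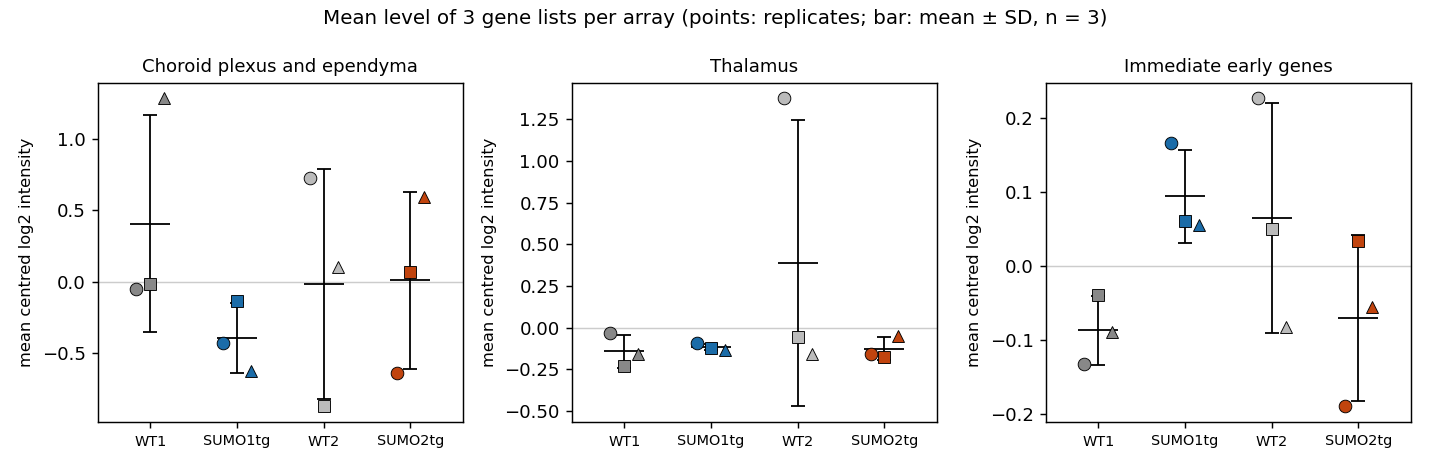
Mean centred log2 level (y axis) of choroid plexus and ependyma markers, thalamic markers and immediate early genes on each of the 12 arrays, by group (x axis). Points are arrays, bars are group means and error bars are ± 1 SD (n = 3). WT1 array 3 (1.29) and WT2 array 1 (0.73) have the highest choroid plexus levels, and WT2 array 1 (1.38) has the highest thalamic level.

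The changes of the lines were set against each other to ask which genes differed in their change between SUMO1 and SUMO2 transgenic mice, as the SUMO1tg change from WT1 minus the SUMO2tg change from WT2. Penk differed by -1.18 ± 0.21 log2 (2.27-fold, SE), the largest difference among the 20 genes named here by rank of p, and Pcdhb6 shared its adjusted p at -0.81 ± 0.14 (limma, 0.386 for both). Larger differences that did not pass included markers of choroid plexus and thalamus, at -2.80 for Ttr, -2.35 for Kcnj13 and 2.00 for Slc17a6. Neither Penk nor Pcdhb6 passed, so the Penk change was not shown to differ between the lines. Between the transgenic groups themselves, SUMO1tg minus SUMO2tg, which leaves out the wild types, Penk differed by -1.33 (limma adjusted p = 0.00791) and Pcdhb6 by -0.30 (limma adjusted p = 0.792). Mc4r (-0.72), Cyp2d40 (-0.58), Plp2 (-0.53), Padi2, an enzyme that converts arginine to citrulline in proteins (-0.51), Tafa1 (-0.41), Pcdhb2 (-0.40), Emp1 (-0.30) and the transcription factor Nfia (-0.29) followed in that direction without passing. In the other direction, Zmat4 (0.73), Gfra1 (0.64), D3Ertd751e (0.60), DQ267101 (0.58), Bnip5 (0.47), Pvr (0.46), Hlf (0.44), Kcnab3 (0.43), Akr1b10 (0.42) and Clic5 (0.41) ranked highest, also without passing. With choroid plexus and thalamic marker levels as covariates, Zmat4 differed by 0.44, Gfra1 by 0.38, DQ267101 by 0.37, Hlf by 0.29 and Cyp2d40 by -0.36, and Nfia differed by -0.17 with the mean over its probe sets. In limma, 0 of 14526 probe sets passed, 0 did so without moderated variances, and 694 had an unadjusted p under 0.05, where chance gives 726.3. Of the lists, immediate early genes (median 0.23, 30 of 34 higher, camera adjusted p = 2.38e-07, 2 genes adjusted over the list alone) and choroid plexus markers (median -0.75, 19 of 20 lower, camera adjusted p = 1.08e-06, 0 adjusted over the list alone) differed, each with an adjusted p = 0.877 with an estimated correlation. The choroid plexus median was -0.23, -0.38 and -0.46 without WT1 array 3, WT2 array 2 and SUMO2tg array 3. Across 13208 genes, which are not independent replicates, the changes of the lines had a Pearson r of 0.0438 and a Spearman rho of 0.0522. At an unadjusted p under 0.05 in both lines there were 50 genes, 25 higher in both where independent lists give 15.4, and 3 lower in both where they give 3.39. No gene passed the adjusted threshold in both.

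WT2 was compared with WT1 to give the background between the sets of wild types. Scg5, which encodes the chaperone 7B2 of a prohormone convertase, fell in WT2 by 0.61 on the log2 scale (SE 0.06, n = 3 per group, limma adjusted p = 0.00159) on its probe set (10485955), a ratio of 1.52 between WT1 and WT2. Pla2g4e, a cytosolic phospholipase, fell by 0.91 (SE 0.12, a ratio of 1.88, limma adjusted p = 0.0339) on its probe set (10486403). All 3 WT2 arrays lay below all 3 WT1 arrays for both genes. Tbc1d8b (-0.44), Pcdhb6 (-0.50) and Pcdhb3 (-0.31) ranked next among genes with a lower mean, and Lrrc2 (0.33), Banp (0.45), the interferon-induced gene Ifi35 (0.39), Lzts2 (0.27) and the glycosyltransferase Galnt13 (0.65) among those with a higher mean, none of them past the threshold (lowest limma adjusted p = 0.121, Tbc1d8b). These 2 were the only probe sets of 14526 to pass in limma, and 1229 had an unadjusted p under 0.05, 960 higher and 269 lower in WT2, where chance gives 726.3. The groups did not overlap on 11.4% of probe sets, and chance gives 10%. Both calls were lost with only the wild types in the fit (limma adjusted p = 0.266 for each). The Pla2g4e call was also lost without WT1 array 1 (limma adjusted p = 0.0654), WT1 array 2 (0.222) and WT2 arrays 1, 2 and 3 (0.0941, 0.156 and 0.173) and without the filter on dim probe sets (0.0508), while Scg5 kept its call in these fits.

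**Figure D3:**
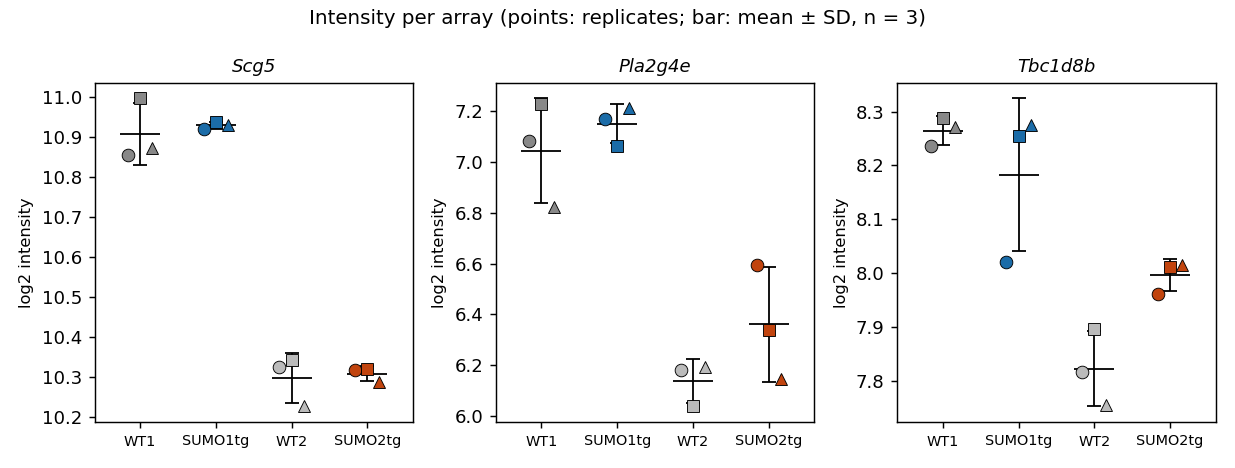
Log2 intensity of Scg5, Pla2g4e and Tbc1d8b (y axis) on each of the 12 arrays, by group (x axis). Points are arrays, bars are group means and error bars are ± 1 SD (n = 3). Scg5 lies between 10.2 and 10.3 on the WT2 and SUMO2tg arrays and between 10.9 and 11.0 on the WT1 and SUMO1tg arrays.

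Between the wild types, 6 lists were shifted. Choroid plexus markers were lower in WT2 (19 of 20, median -0.35, camera adjusted p = 0.000361), as were heat shock genes (18 of 25, median -0.05, camera adjusted p = 0.012), each with an adjusted p = 0.881 with an estimated correlation. Thalamic markers (14 of 15, median 0.52, camera adjusted p = 0.012), clock genes (18 of 19, median 0.11, 0.012), glucocorticoid-responsive genes (18 of 18, median 0.15, 0.0225) and immediate early genes (29 of 34, median 0.11, 0.0448) were higher, each with an adjusted p = 0.881 with an estimated correlation. Clock, glucocorticoid-responsive and immediate early genes vary with the time of day, and the labelled times, which may be a filled-down series, also differ between WT1 and WT2. In fry, 0 lists passed. Over all alternatives, fry and the estimated correlation included, the immediate early call was lost in 9 of 20 and the glucocorticoid-responsive call in 6 of 20. The clock call was lost in 5 of 20 and the heat shock call in 4 of 20. The thalamic call was lost in 5 of 19 and reversed in 1, and the choroid plexus call was lost in 2 of 19 and reversed in 2. The thalamic level was 1.38 on WT2 array 1 and between -0.23 and -0.04 on the other wild-type arrays. The thalamic median was -0.01 without that array (adjusted p = 0.48), 0.51 without WT1 array 1 (adjusted p = 0.164) and 0.80, still called, without WT2 array 3. The choroid plexus level was 1.29 on WT1 array 3, and the choroid plexus median was 0.07 without that array (adjusted p = 0.957) and 0.03 without WT2 array 2 (adjusted p = 0.51). It was -0.71 without WT2 array 1, -0.59 without WT1 array 1 and -0.56 without WT1 array 2, all still called. The clock call ended without WT1 array 1 (median 0.10, adjusted p = 0.154) or WT2 array 1 (0.10, adjusted p = 0.0646). The immediate early call ended without WT1 array 1 (0.12, adjusted p = 0.627) or WT2 array 1 (0.07, adjusted p = 0.518), with a median of 0.17 without WT2 array 3. The glucocorticoid-responsive call ended without WT1 array 1 (0.14, adjusted p = 0.364) or WT2 array 3 (0.10, adjusted p = 0.638), with a median of 0.22 without WT1 array 2. The heat shock call ended without WT2 array 3 (-0.0076, adjusted p = 0.397), with medians of -0.03 without WT1 array 1 and -0.08 without WT2 array 1. Adjusted over the list alone, 2 clock genes, 1 glucocorticoid-responsive gene and 0 genes of the other 4 lists passed. Fry's test of change in either direction passed for clock genes (adjusted p = 0.034) and oligodendrocyte precursor markers (adjusted p = 0.000827). Myelin markers had a median of 0.14 (camera adjusted p = 0.169).

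The other gene lists were not shifted in either line in camera, and the lowest adjusted p among them was 0.151 in SUMO1tg (neurogenesis and immature neurons) and 0.0828 in SUMO2tg (CA1 pyramidal neurons). For reading their medians, that over all tested probe sets was 0.03 in SUMO1tg and 0.0018 in SUMO2tg. Among hippocampal neurons, CA1 markers had a median of 0.19 in SUMO1tg (10 of 12 higher) and 0.14 in SUMO2tg (9 of 12 higher), and dentate granule neuron markers had medians of -0.02 and 0.03 over 17 genes. CA3 and CA2 markers had a median of -0.05 and interneuron markers of 0.01 in SUMO2tg. Immature neuron and neurogenesis genes had medians of 0.07 in SUMO1tg and 0.0090 in SUMO2tg over 14 genes, and neocortical markers 0.06 and -0.05 over 17 genes. Among synaptic genes, glutamate receptors and postsynaptic density proteins had medians of 0.0052 in SUMO1tg and 0.02 in SUMO2tg over 40 genes, presynaptic vesicle release genes 0.05 and -0.0021 over 32 genes, and voltage-gated ion channels 0.03 and 0.0010 over 32 genes. Among glia, astrocyte markers had medians of 0.02 and -0.03 over 19 genes, oligodendrocyte precursor markers 0.02 and 0.01 over 11 genes, and microglial markers 0.02 and -0.01 over 18 genes. Oxidative phosphorylation genes had medians of 0.03 in SUMO1tg and 0.02 in SUMO2tg over 47 genes, and ribosomal protein genes 0.03 and 0.02 over 36 genes. Glucocorticoid-responsive genes had medians of 0.12 and -0.03 over 18 genes, interferon-stimulated genes 0.06 and 0.04 over 13 genes, and DNA damage and p53 target genes 0.07 and -0.0051 over 15 genes. Sex-linked transcripts had medians of 0.05 and 0.0027 over 8 genes, and the 2 tested blood cell genes, too few for a list test, -0.11 and 0.07. In SUMO1tg, clock genes had a median of 0.03, endothelial and mural cell markers 0.03, thalamic markers -0.08 and striatal markers -0.03, and in SUMO2tg heat shock genes had a median of -0.03. No gene of the lists in this paragraph passed in SUMO1tg when adjusted over its list alone (0 in each), and in SUMO2tg none did except Penk among the 11 striatal markers.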

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

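The fits in this part without WT1 array 3 and WT2 array 1 and with marker levels as covariates, and the splits counted at unadjusted p, were chosen after the results had been seen. Immediate early genes stood out because their changes differed between the lines in the test of the difference: they were higher in SUMO1tg than in WT1 and lower in SUMO2tg than in WT2, with a median difference of 0.23 log2 over 34 genes (30 of 34 in this direction, camera adjusted p = 2.38e-07, but adjusted p = 0.877 with an estimated correlation). With the choroid plexus and thalamic marker levels as covariates the median difference was 0.19, just over the 0.8 of its size set beforehand as speaking against carried-over tissue, but over fits without 1 array each it kept from 62% to 110%, so carried-over choroid plexus or thalamus and the transgenes cannot be told apart here. Without WT1 array 3 and WT2 array 1 it was 0.17, between the bounds set beforehand, which leaves a part for these arrays open. Of 100 splits of the arrays within the pairs, the real one included, 92 gave as many differing lists as the real 2 and the highest other split gave 13, so chance is not excluded. A biological difference between the lines and a difference in collection time, whose label may be a filled-down series and is confounded with the groups, remain open as untested, and against WT1 the SUMO2tg median was 0.02. Both sets of wild types enter this difference. The list's median for WT2 minus WT1 lay between 0.07 and 0.17 without each array in turn. Part of the difference thus lies between the wild types.

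Choroid plexus and ependyma markers stood out in the same test of the difference between the lines, with a median difference of -0.75 log2 over 20 genes (19 of 20 in this direction, camera adjusted p = 1.08e-06, adjusted p = 0.877 with an estimated correlation) and of -0.23 without WT1 array 3. The list's mean centred level ranged from -0.88 to 0.73 within WT2 and from -0.65 to 0.60 within SUMO2tg. Both sets of wild types enter the difference, and the median of WT2 minus WT1 lay between -0.71 and 0.07 without each array in turn. Carried-over choroid plexus and a difference between the lines therefore cannot be told apart here.

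For the counts of genes and lists, the 6 arrays of a pair allow 10 splits into 3 and 3, too few for a share under 0.05. SUMO1tg against WT1 gave 0 probe sets at an adjusted p under 0.05 in limma (1087 at an unadjusted p under 0.05), and the highest other split gave 1. A real count of 0 is reached by 10 of 10 splits whatever the data, so this comparison says nothing about chance. At an unadjusted p under 0.05 the highest other split gave 2100, and 4 splits gave as many as the real one. Its 7 shifted lists compare with up to 10 in another split, and 7 splits gave as many. SUMO2tg against WT2 gave 6 shifted lists, the highest other split gave 9, and 7 splits gave as many. For the difference between the lines, 0 probe sets passed in limma (694 at an unadjusted p under 0.05), the highest other split gave 1, and 100 of 100 splits reach a count of 0 whatever the data. At an unadjusted p under 0.05, 50 of 100 splits, the real one included, gave as many and the highest other gave 1559, so chance is not excluded for that count.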

How the results depend on the processing

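Fits without WT1 array 3 and WT2 array 1, with marker levels as covariates and with Xist as a covariate were chosen after the data had been examined. The 0 probe sets of SUMO1tg against WT1 and of the difference between the lines stayed at 0 in limma in every fit adjusted for multiple tests (1087 and 694 at an unadjusted p under 0.05). The 1 of SUMO2tg against WT2 became 0 with only the groups compared, without the filter on dim probe sets, after quantile normalization, with a variance trend, over all rows of the table and without moderated variances (539 at an unadjusted p under 0.05), 5 against WT1 and 4 against all 6 wild types. The 2 of WT2 against WT1 became 0 with only the groups compared (1229 at an unadjusted p under 0.05) and 1 without the filter, with probe sets above the median only, with the replicate block, over all rows of the table and with Xist as a covariate. Without each array in turn, SUMO2tg against WT2 gave 0 to 0, WT2 against WT1 gave 1 to 2, and the shifted lists numbered 2 to 7 in SUMO1tg and 5 to 8 in SUMO2tg. Unadjusted p without moderated variances gave 954, 550, 636 and 1122 probe sets for SUMO1tg, SUMO2tg, the difference and the wild types, and unadjusted p with a 1.2-fold minimum gave 298, 152, 469 and 275, which follows from leaving out the adjustment. The 7 lists of SUMO1tg became 3 with probe sets above the median only and so fewer genes, 3 without WT1 array 3 and WT2 array 1, 4 with covariates, and 0 with an estimated correlation and with fry. The 6 of SUMO2tg became 0 with an estimated correlation and with fry.

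Sumo2 in SUMO1tg was near 0 and turned to -0.013 with centred arrays, -0.034 with array weights and -0.019 with the mean over its probe sets, and lay between -0.05 and 0.044 without each array in turn. Sumo3 in WT2 against WT1 lay between -0.043 and 0.084 in the same way, and Sumo2 in WT2 against WT1 between -0.11 and -0.018. Sumo3 in SUMO1tg lay between 0.074 and 0.20 without each array in turn. Against WT1 in place of WT2, SUMO2tg values turned to 0.053 for Kcnab3, 0.0023 for Egr2, 0.10 for Hlf, 0.051 for Esam, 0.047 for Vtn, 0.061 for Slc17a6, 0.018 for the immediate early median and 0.056 for the clock median. With marker levels as covariates, SUMO1tg values turned to 0.12 for Cacng5, 0.065 for Trf, 0.029 for Cnp, 0.032 for Igf2, 0.083 for Slc13a4, 0.13 for Igfbp2, 0.038 for CA3 and CA2, 0.094 for myelin and 0.041 for meningeal markers. Myelin markers were called in that fit with their median above 0 (camera adjusted p = 0.0182). The CA3 and CA2 (camera adjusted p = 0.86) and meningeal markers (0.974) were not called. Without WT1 array 3, alone or with WT2 array 1, the SUMO1tg myelin median was 0.027, within -0.20 to 0.027 over single arrays, and without WT2 array 1, alone or with WT1 array 3, the SUMO2tg thalamic median was 0.0044, within -0.81 to 0.0044. Over single arrays, the medians of WT2 against WT1 lay between -0.7139 and 0.0725 for choroid plexus (0.0315 without WT2 array 2) and between -0.0144 and 0.7974 for thalamic markers. Where the settings themselves do not show it, the cause was not tested. Of 2640 alternative values of 135 results on named genes, 2598 kept direction and side of the threshold, 20 lost and 3 gained a call and 19 reversed. All 20 losses fell on the genes that had passed: Penk in SUMO2tg (10 of 20 alternatives) and, between the wild types, Pla2g4e (9 of 17) and Scg5 (1 of 18). The other results had not passed, so their staying on that side of the threshold says little about how stable they are. Of 444 list medians, 330 kept both, 102 lost the call and 12 reversed. Penk stayed between 1.10 and 1.36 (adjusted p from 0.0029 to 0.276).

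Replicate numbers showed no clear pairing of the animals. With each group's mean subtracted, arrays of 1 number in WT1 and SUMO1tg had correlations of -0.01, -0.07 and -0.04 across probe sets. Those in WT2 and SUMO2tg had -0.20, 0.14 and 0.08. So few values cannot exclude a pairing. With the replicate block, 0, 1, 0 and 1 probe sets passed in limma for SUMO1tg, SUMO2tg, the difference and the wild types, 7 and 6 lists were shifted, Sumo2 in SUMO2tg was 0.17, and Pla2g4e had an adjusted p = 0.0793 (0.0104 to 0.266 over its alternatives). Signal over background was not measured, so how far background limits the changes of dim genes is not known, and leaving the dim probe sets in raised the adjusted p of Penk to 0.056.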

Other observations

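The tests of striatal markers, of Penk between the wild types, of the transgenic siblings, of chromosomes and of the segment between Scg5 and Pla2g4e were chosen after the results they address had been seen. Setting WT2 and SUMO2tg together against WT1 and SUMO1tg, 6 mice against 6, 4 probe sets passed in limma: Scg5 (-0.61 ± 0.04 log2, SE, adjusted p = 2.76e-05), Pla2g4e (-0.85 ± 0.08, adjusted p = 0.00174), Lrrc2 (0.29 ± 0.04, adjusted p = 0.0471) and Penk (0.74 ± 0.11, adjusted p = 0.0471). For the first 3 of these genes the arrays of the sides did not overlap. This contrast averages the wild-type and the transgenic difference, and Penk differed by 0.15 between the wild types and by 1.33 between the transgenic groups. Its place here is thus not a difference shared by both. Next came Tbc1d8b (-0.32), Banp (0.35), Galnt13 (0.60), Gm1976 (0.23) and Pisd-ps2 (-0.41), with an adjusted p = 0.071. Between the transgenic groups alone, SUMO2tg minus SUMO1tg, 2 probe sets passed in limma, Scg5 (adjusted p = 0.0013) and Penk (1.33, adjusted p = 0.00791), and Pla2g4e differed by -0.79 (adjusted p = 0.0615).

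Of the 100 genes with the lowest p in SUMO2tg against WT2, 13 had another of the 100 within 10 genes on a chromosome, above the 95th percentile of 11 in 1000 random draws of tested genes (median 6, permutation test p = 0.018, adjusted p = 0.0719 over 4 comparisons). Among the 13 were the protocadherins Pcdhb6 (0.61), Pcdhb7 (0.32), Pcdhb13 (0.28) and Pcdhb19 (0.33) of 1 gene cluster, and Penk was not among them. In SUMO1tg against WT1 the number was 6. Which wild types are the littermates of SUMO2tg is not settled by these numbers.

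Ttr, the transthyretin gene of the choroid plexus, ranged from 7.80 log2 on WT2 array 2 to 14.0 on WT1 array 3, and Kcnj13 from 5.17 to 10.5 on the same arrays. Eif2s3y, Kdm5d and Uty, which lie on the Y chromosome, were low (15.3 to 26.1 in intensity) on the 4 arrays with high Xist and at 154 or above on the 8 other arrays.

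The first pattern weighed is Penk in SUMO2tg, where carried-over striatum would bring its other markers too, but the 10 other striatal markers tested, among them Drd1, Drd2 and Ppp1r1b, had a median change of -0.026 (SD 0.20), below 0.61, which is 50% of the Penk change, by more than their spread. With choroid plexus and thalamic marker levels as covariates Penk differed by 1.12 (95% interval 0.90 to 1.34), which argues against those tissues as its source. The 6 arrays allow 10 splits, too few for a share under 0.05: the real split called 1 probe set and the highest other 0. Whichever wild types are the littermates, a difference between their families would need Penk to differ between WT1 and WT2, but it differed by 0.15 ± 0.15 (SE), while SUMO2tg lay 1.22 above WT2 and 1.36 above WT1, which argues against it. An effect of the SUMO2 transgene remains open as untested, beside anything else that only the SUMO2tg animals share, such as collection time.

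The other pattern weighed is Scg5 and Pla2g4e between the wild types: with choroid plexus and thalamic marker levels as covariates Scg5 differed by -0.65 (95% interval -0.81 to -0.49), which argues against those tissues, and 10 splits were again too few for a share under 0.05 (real 2 probe sets, highest other 0, 1 split as large). Scg5 also differed by -0.62 between SUMO2tg and SUMO1tg, arrays not used for the wild types, which is consistent with a difference between families that transgenic siblings share, although across all genes the wild-type and transgenic differences had a Pearson r of 0.0172 and a Spearman rho of 0.0593. Families here are WT2 with SUMO2tg and WT1 with SUMO1tg, as the series description pairs them. The litter labels give SUMO2tg the number of WT1, so this grouping is not settled. Ranking genes between these families also takes in genes that differ mainly between the transgenic groups. Penk and Padi2 (0.01 between the wild types, 0.53 between the transgenic groups) are among the 100 used below. Of the 100 genes with the lowest p between families, Scg5 and Pla2g4e left out, 16 of the 97 placed lie on the chromosome of these genes (median 8 and 95th percentile 12 in 1000 random draws), but the next largest excesses were 11 against 5.61 expected and 7 against 3.38, and over all chromosomes none passed (exact hypergeometric test, adjusted p = 0.0809, 0.266 and 0.385), so a difference limited to 1 chromosome is not shown and stays open. Between Scg5 and Pla2g4e, 8 of 46 tested genes (17.39%, against 7.84% of all) had an unadjusted p under 0.05 between families, as many as 4.44% of the other runs of 46 neighbouring tested genes (median 3, 95th percentile 7), which is consistent with a differing segment there, although these runs overlap. The number of the 100 with another of them within 10 genes was 10 (median 6, 95th percentile 11, permutation test p = 0.125). A number at or below the 95th percentile was set beforehand to count against differing segments, and by that bound this result does. The bound was questioned only after the result was seen. Since 10 lies above the median of random draws, the number cannot exclude some segments elsewhere.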
